A study of Bos taurus with 16 samples.

How the data were processed

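RNA was measured in 16 cultures of bovine (Bos taurus) luteal cells, 4 groups of 4 samples: control, interferon tau (IFNT), prostaglandin F2 alpha (PGF2A), and both together (IFNT+PGF2A). Per the labels' protocols, triplicate wells of each treatment were pooled before total RNA was extracted, and the libraries were sequenced on the DNBSEQ platform as 100 bp read pairs. The labels number the samples of each group from 1 to 4 and do not say whether a number stands for 1 animal or 1 culture, so p-values measure the spread between these samples only. Group and number were taken from the sample titles. No column of the tables belonged to a sample outside the labels.

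The submitters' processing notes name HISAT2 2.0.4, Bowtie2 2.2.5, RSEM 1.2.8 and DESeq2, the last without a version, and give no order or settings. The genome build and gene annotation are not given in the sources used here. Strand use in counting is not stated either, so reads of a gene and of an antisense or overlapping neighbour cannot be separated. RSEM shares out reads that match several genes, so values of near-identical copies are uncertain; this concerns the alpha globin genes HBA and HBA1, the class I BOLA genes and other members of gene families such as the IFIT and GBP genes.

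Per the file headers, 7 deposited tables were used. In 4 of them the authors compared a pair of groups and gave the mean level, a log2 fold change with its standard error, a test statistic (a score), a p-value and an adjusted p-value. The other 3 hold the main effect of PGF2A, the main effect of IFNT and the interaction, each with a statistic and p-values but no fold change. In the table of PGF2A and IFNT+PGF2A the sign of the authors' deposited statistic was opposite to that of the fold change in every row, so directions were taken from the fold change and the group values. All tables also hold values per sample. These deposited values are a signal per gene, namely read counts divided by 1 size factor per sample, as the values themselves showed: 100% of them were whole multiples of 1 read within 0.001 reads. The pairwise tables were scaled separately on their own 8 samples, while the interaction tables were scaled on all 16 samples together; only the latter were used here for levels and tests.

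The 16-sample table listed 18705 genes, 12 of them at 0 in every sample. Gene IDs were matched to the RefSeq gene table of assembly ARS-UCD2.0 for names alone: 17768 matched and 937 did not. The table's own name was kept for 590 genes that carry only a number. A spreadsheet had turned 25 names into dates, and all 25 were restored by gene ID. Recovered reads assigned to genes came to 23786067 to 25906276 per sample, and size factors ran from 0.963 to 1.071. At this depth a gene with 0 reads in a whole group can still have had up to 3 reads over that group; this limit and any range from counts cover counting error only, since the reads carry no molecular identifiers.

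Because the values are normalized, the main test was limma 3.58.1 with an intensity trend (R 4.3.3) on log2(normalized count + 0.5), with 1 mean per group, all 16 samples sharing 1 estimate of the spread, and no block. Fold changes are therefore on that log2 scale and understate the change of low genes. Genes with a normalized count of at least 10 in at least 4 samples were tested (14122 genes), and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The test, the samples in the fit, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined; the trend and the filter were not. On simulated data with 200 changed genes (5 draws of 14053 to 14063 genes), the unblocked test of PGF2A against control recovered 25.1% of 1.5-fold, 66.9% of 2-fold and 93.3% of 4-fold changes. With the replicate number as a block it recovered 67.8%, 93.4% and 99.1%, and 3.67% of its calls were false. Of the blocked calls, 5.30% were false for IFNT against control and 5.25% for IFNT+PGF2A against PGF2A. Changed genes were drawn above a minimum mean level, so recovery of the lowest genes was not measured. The simulation gave each number the same shift in all groups, the form that the block assumes, with the spread taken from the blocked design. Treatment responses that differ between numbers entered only as random spread, so the blocked rates hold for data of that form. For the interaction the unblocked test recovered 2.99%, 35.5% and 79.4% and the blocked test 30.1%, 75.8% and 97.3%.

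Whether the sample numbers pair the samples was checked before any calls were compared, by correlating each sample's deviations from its group mean over 14122 genes. The 24 pairs with the same number in different groups had correlations of 0.352 to 0.719 (median 0.640), while the highest of the 72 pairs with different numbers was 0.0402. Each of the 16 samples correlated best with a sample of its own number. The numbers therefore pair the samples, from the data and not from the labels, and results of the fit with the replicate number as a block are given beside the unblocked ones where they change the call of a gene or list in the text or move a count of calls in it by more than 1.5 times. For counts adjusted over the list alone in the IFNT comparisons, the report gives only how far that adjustment moved the blocked counts.

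For each of the 4 pairs of groups, the interaction and both main effects, the genes past the threshold were counted. Gene lists, 16 of pathways and 9 of cell type markers, were tested with camera (preset correlation 0.01), adjusted over 125 combinations of list and comparison. In lists such as the class I genes, 1 symbol can match several gene IDs, so that more members were tested than the list names. Genes named in the text follow a rule: among genes with a symbol, an adjusted p under 0.05 and a mean of at least 50, the 8 largest rises and 8 largest falls per comparison; up to 4 members per list with the smallest adjusted p; and, whatever their p, a fixed set that includes ISG15, MX1, MX2, OAS2, IRF9, STAR, CYP11A1, HSD3B1, LHCGR, PTGFR, PTGS2, NR4A1, CXCL8 and VEGFA. Some genes that the rule picks are not reported here. For the comparisons of PGF2A the rule was also applied to the blocked fit, a choice made after seeing the data. Any gene named outside the rule is said to be so.

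Alternatives included other filters, pseudocounts, thresholds and sample sets, a null of at most 1.2-fold, statistics rescaled by their robust spread, and leaving out each sample in turn. Added after seeing the data were edgeR 4.0.16 (quasi-likelihood test) and DESeq2 1.42.0 on the recovered whole reads, the authors' deposited adjusted p-values, fits without number 4, and further set tests. The other pseudocounts and the correlations of effects over genes called with the block were also added then. No reference genome was used, so no coordinates are given.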

Results

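The data were gene-level RNA-seq values from primary cultures of mixed luteal steroidogenic cells, the progesterone-producing cells of the corpus luteum, taken from cows between cycle days 10 and 12. Cells in medium with luteinizing hormone were treated for 24 hours with nothing (control), with IFNT at 1 ng/mL, with PGF2A at 10 ng/mL, or with both, giving 4 samples in each of 4 groups. IFNT is the signal by which the ruminant conceptus announces pregnancy, and PGF2A is the hormone that ends the life of the corpus luteum; the series title asks how each affects gene expression in these cells. Between 23786067 and 25906276 reads were assigned to genes per sample, the 10 highest genes taking 6.21% to 10.4% of them.

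On the first principal component, which held 49.8% of the variance, all 8 samples with IFNT lay between 33.33 and 58.25 and all 8 without it between -59.29 and -40.45. The second component (17.2%) set number 4 of every group apart, at -29.09 to -70.11 against -1.04 to 29.26 for the other numbers. In number 4 the median pericyte and smooth muscle marker was higher than in numbers 1 to 3 by 0.93 ± 0.15 (log2, SD over 4 groups), while that of the neutrophil and red cell markers differed by -1.42 ± 0.48. The latter list includes the alpha globin genes HBA and HBA1. Over all libraries there were only 0.0464 beta globin reads per 100 alpha globin reads, so this difference cannot be read as fewer blood cells.

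**Figure D1:**
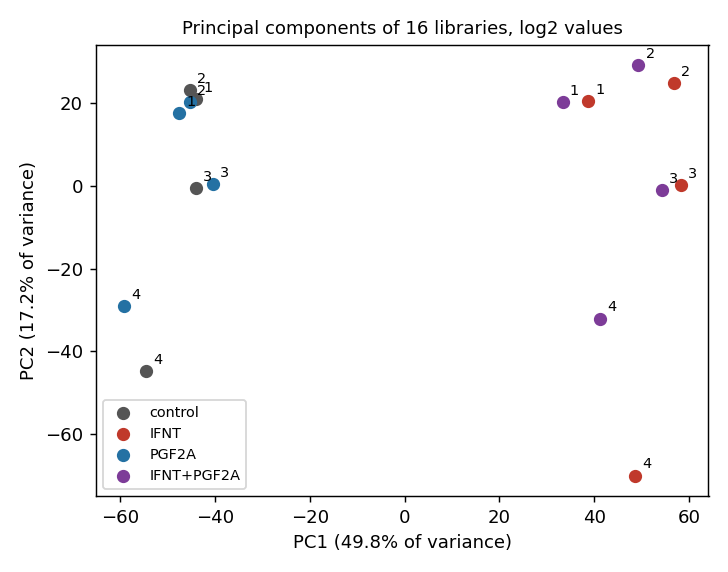
Principal components of the 16 libraries from log2 values of 14122 genes; each point is a library, coloured by group and marked with its sample number. Libraries with IFNT lie to the right on the first component (49.8% of variance), and number 4 of each group lies lowest on the second (17.2%).

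The largest responses to IFNT alone were in interferon-response genes. All 54 tested members of the list of classical interferon-stimulated genes rose against control, by a median of 4.08 on the log2 scale. MX2, an antiviral GTPase, went from 150.4 ± 100.4 normalized counts in control to 62340 ± 26760 with IFNT (SD, n = 4; log2 change 9.24, SE 0.95, adjusted p = 2.9e-06). ISG15, a ubiquitin-like modifier, went from 361 ± 164 to 33930 ± 7474 (6.67, SE 0.65, adjusted p = 1.7e-06), and MX1 from 1442 ± 825 to 80080 ± 17130 (5.99, SE 0.74, adjusted p = 2.3e-05). The transcript of CYP11A1, the side-chain cleavage enzyme that begins steroid synthesis, fell from 33340 ± 7166 to 16420 ± 3623 (-1.02, SE 0.21, adjusted p = 0.0021), lower in 4 of 4 same-number pairs.

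The test of IFNT against control called 3384 of 14122 genes in limma, 1851 higher and 1533 lower. With the replicate block the count was 6140 (3015 higher, 3125 lower), and 1138 unblocked calls were at least 2-fold, 844 of them higher. Among the largest rises by the naming rule were MX2, PLAC8B (8.67), IFIT3 (8.52), RSAD2 (8.29), GBP4 (7.73), OAS2 (7.70) and IFIT2 (7.64). The largest falls were smaller and included the potassium channel subunit KCNF1 (-3.30), INSYN2 (-2.88), SYT6 (-2.42), SCRN1 (-2.36), the oxysterol receptor GPR183 (-2.32), the growth factor FGF1 (-2.30) and SAMD11 (-2.18). 1 further gene, chosen after its values were seen, is listed only by its number, 786073. It had 0 reads in all 4 control and all 4 PGF2A libraries and 7591 to 12102 reads in the IFNT libraries, a mean of 9423 ± 2281, at least 13033-fold higher than the limit of 3 reads over the control group.

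The interferon-stimulated list rose with a camera adjusted p of 4.4e-56 (adjusted p = 0.062 with an estimated correlation); adjusted over the list alone, again 54 of 54 passed. Its members with the smallest adjusted p were ISG20 (4.10), CMPK2 (6.22), IFI35 (3.01) and HERC5 (3.77). Of 29 interferon receptor, JAK-STAT, IRF and SOCS genes, 13 rose and 3 fell, 15 and 5 with the replicate block, and 14 and 4 when adjusted over the list alone (camera adjusted p = 0.00021 and adjusted p = 0.60 with an estimated correlation). Transcription factors of the type I interferon pathway rose, STAT2 by 2.37, IRF9 by 2.41, IRF3 by 1.79 and IRF7 by 3.75. Genes of MHC class I antigen presentation rose in 19 of 21 cases, and in 21 of 21 when adjusted over the list alone (camera adjusted p = 9.9e-20 and adjusted p = 0.027 with an estimated correlation, 0.11 with the block and an estimated correlation). TAP1, a peptide transporter, rose by 3.34, the immunoproteasome subunit PSMB8 by 2.56, the proteasome activator PSME1 by 1.65 and B2M, the class I light chain, by 2.19. Of 11 class II genes 7 rose, also when adjusted over the list alone (camera adjusted p = 3.5e-06 and adjusted p = 0.17 with an estimated correlation), among them BOLA-DMB (4.72), the protease CTSS (3.33), BOLA-DRA (4.28) and the invariant chain CD74 (3.17).

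Of 40 genes for inflammatory cytokines, chemokines and adhesion, 20 rose and 0 fell, 25 and 1 with the replicate block, and 22 and 0 when adjusted over the list alone (camera adjusted p = 2.9e-06 and adjusted p = 0.26 with an estimated correlation). CSF1 rose by 1.33, ICAM1 by 1.12, CCL8 by 5.10 from 2.63 ± 1.61 to 119.7 ± 83.3 counts, and CXCL16 by 0.72. Of 34 apoptosis genes 14 rose and 4 fell, 15 and 5 when adjusted over the list alone (camera adjusted p = 0.0039 and adjusted p = 0.040 with an estimated correlation, 0.056 with the block and an estimated correlation). The rises included the inflammatory caspase CASP4 (2.23), the death receptor FAS (1.52) and CASP8 (0.83). The cholesterol list of 37 genes had 6 rises and 0 falls, also when adjusted over the list alone (camera adjusted p = 0.015 and adjusted p = 0.96 with an estimated correlation). NPC2 rose by 0.68, DHCR7 by 0.70, FDPS by 0.59 and GGPS1 by 0.51; with the replicate block 20 rose and 2 fell, and the blocked adjusted p with an estimated correlation was 0.038.

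Steroidogenesis genes moved both ways. Of 32 tested, 2 rose and 5 fell, also when adjusted over the list alone, and the list did not pass (camera adjusted p = 0.43). STARD3, a cholesterol-binding protein of late endosomes, rose by 0.95 and the progesterone receptor PGR by 1.27, while CYP11A1 and the transcription factor NR5A1 (-0.76) fell. STAR, which delivers cholesterol to mitochondria, was 3988 ± 2192 in control and 2073 ± 1140 with IFNT (-0.97, SE 0.54, adjusted p = 0.22), and with the replicate block its fall passed (adjusted p = 1.7e-06; lower in 4 of 4 pairs). HSD3B1 behaved alike (-0.48 and adjusted p = 0.15, or 0.0035 with the block), and blocked counts for the list were 6 higher and 11 lower. LHCGR (-0.31, adjusted p = 0.55) and PTGFR, the PGF2A receptor (0.16, adjusted p = 0.87), did not pass in either fit. Also past the threshold with the block alone were PTGS2 (-0.78, adjusted p = 0.00027), NR4A1 (-0.89, adjusted p = 9.7e-05), VEGFA (-0.72, adjusted p = 0.00073) and CXCL8 (-0.23, adjusted p = 0.032).

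The remaining pathway lists did not pass the unblocked set test, and their members went both ways. Of 22 prostaglandin genes 2 rose and 1 fell (8 and 5 with the replicate block), including CBR3 (1.15) and PTGES2 (-0.82). Among 33 immediate early and NR4A genes 4 rose and 3 fell, for example ZFP36, which destabilizes cytokine mRNAs (1.22), and IER3 (-1.12), while with the block 6 rose and 10 fell. Angiogenesis genes had 6 rises and 3 falls of 34 (13 and 8 with the block), with PTX3 at 4.34 and THBS2 at -0.84. The matrix and TGF-beta list had 2 rises and 4 falls of 39 (9 and 9 with the block), BMP2 going from 1111 ± 142 to 398.4 ± 95.8 counts and PLAU rising by 0.92. Endoplasmic reticulum stress genes had 4 rises and 2 falls of 22 (5 and 6 with the block), including MANF (1.47) and DDIT3 (0.94), and oxidative stress and heat shock genes 1 and 4 of 29 (5 and 12 with the block), with GPX4 at -1.12 and NQO1 at -0.66. Cell cycle genes had 2 and 2 of 30 (CCND3 0.65, CCNE1 -0.73) and glycolysis and hypoxia genes 2 and 4 of 27 (ENO2 1.16, PDK1 -1.30). With the replicate block, the cell cycle list (2 higher, 15 lower; camera adjusted p = 0.012) and the glycolysis list (4 higher, 19 lower; camera adjusted p = 0.015) passed as lower, with adjusted p = 0.63 and 0.73 with an estimated correlation. Adjusted over the list alone, the counts of rises and falls were 6 and 4 for angiogenesis, 2 and 2 for the matrix, 5 and 2 for endoplasmic reticulum stress and 1 and 3 for oxidative stress, and the same as above for the other lists. With the block, adjusting over the list alone moved no count of rises or falls of a pathway or marker list by more than 2 in this comparison.

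Markers of other cell types moved too. Of 12 endothelial markers ERG (1.26) and TEK (1.00) rose (camera adjusted p = 0.085), and with the replicate block 9 of 12 rose and the list passed (camera adjusted p = 0.0021 and adjusted p = 0.63 with an estimated correlation). Fibroblast markers split between LUM (-0.61) and THY1 (1.07) among 12 tested, 3 higher and 6 lower with the block, and of 12 pericyte and smooth muscle markers PDGFRB rose (0.47), 5 higher and 1 lower with the block. C1QB rose among 9 macrophage markers (2.60, from 4.07 ± 3.66 to 25.3 ± 14.6 counts), IL2RB among 5 T and NK cell markers (1.34), BLNK among 3 B cell markers (4.04, to 19.1 ± 15.1 counts), and HBA1 among 5 neutrophil and red cell markers (4.26). HBA1 had 24 or 25 reads in each IFNT library and 0 reads in 3 of 4 control libraries, and it shares sequence with HBA. Of 10 large luteal markers PTHLH, the parathyroid hormone-like peptide, rose (2.83), and 0 of 7 small luteal markers passed. Blocked counts of rises and falls were 5 and 1 for macrophage, 2 and 1 for T and NK cell, 1 and 1 for neutrophil and red cell, 3 and 1 for large luteal and 1 and 1 for small luteal markers. Adjusted over the list alone, the unblocked counts of the marker lists were the same. None of these lists other than the endothelial one passed the set test in either fit.

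**Figure D2:**
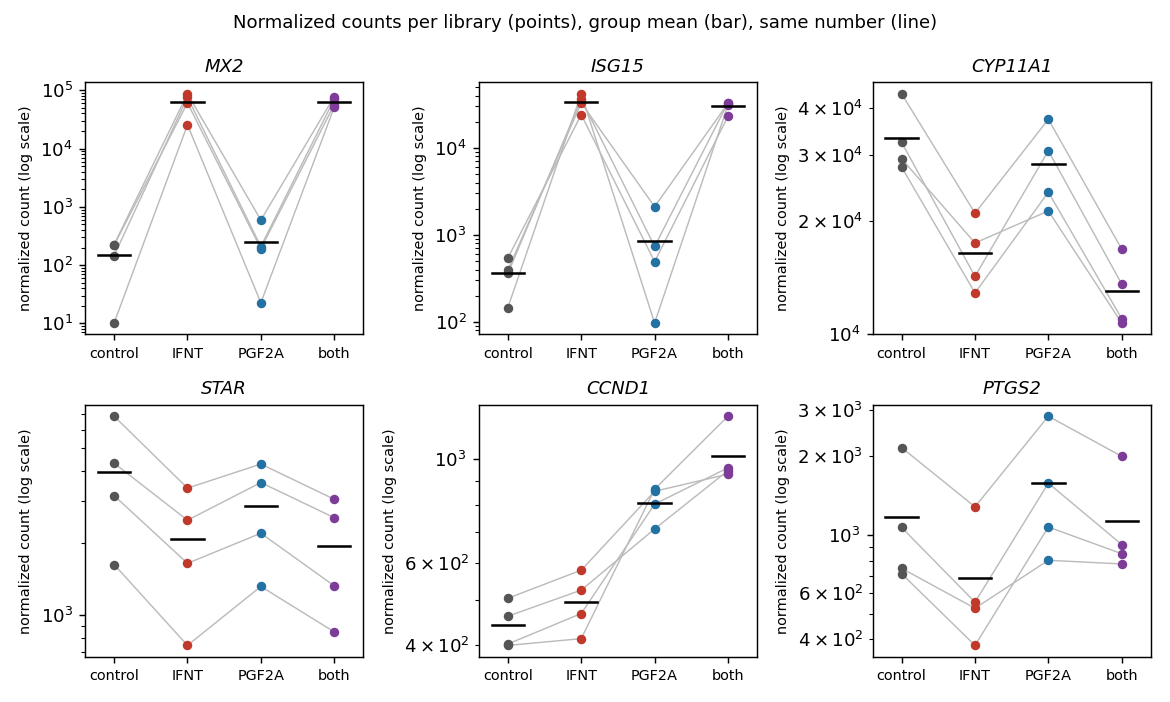
Normalized counts on a log axis for 6 genes in each library (points), by group, with group means (bars) and lines joining samples of the same number. MX2 and ISG15 were at 23100 counts or above in every library with IFNT, CYP11A1 and STAR were lower with IFNT in all 4 same-number pairs, and CCND1 was higher with PGF2A in all 4.

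Few transcripts passed a test of PGF2A alone. No gene passed the unblocked limma test against control; 155 genes had an unadjusted p under 0.05, edgeR on recovered reads also called 0 and DESeq2 called 2. The lowest adjusted p was that of CCND1, cyclin D1, which drives entry into the cell cycle: 441 ± 50.4 normalized counts in control and 807 ± 70.8 with PGF2A (SD, n = 4; 0.87, SE 0.13, adjusted p = 0.072). When the replicate number was a block, 23 genes passed, 16 higher and 7 lower, with 866 genes at an unadjusted p under 0.05. CCND1 rose in 4 of 4 pairs (adjusted p = 0.021). The authors' deposited table for this pair had 5 genes with an adjusted p under 0.05, all higher.

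In the blocked fit the largest rises by the naming rule included the surface glycoprotein CD24 (1.54), the matrix metalloproteinase MMP3 (1.39), the secreted pentraxin NPTX2 (1.05), ADGRE3 (0.88), CCND1, CORO2A (0.87) and the MAP kinase phosphatase DUSP5 (0.82), each higher in 4 of 4 pairs. The secreted phosphoprotein SPP1 rose by 0.63. The falls included the glutathione transferase GSTA2 (-0.65), the tight junction protein CLDN11 (-0.63), CHI3L1 (-0.60), TNN (-0.45), the large luteal marker SCG2 (-0.40) and FAM110B (-0.40), each lower in 4 of 4 pairs. None of these genes passed without the block.

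Steroidogenic transcripts gave small differences that passed in neither fit: STAR -0.44, CYP11A1 -0.25, HSD3B1 -0.35 and LHCGR -0.51 (adjusted p = 1 each without the block; 0.097, 0.67, 0.44 and 1.00 with it). PTGFR was 1057 ± 525 in control and 458.8 ± 122.3 with PGF2A (-1.09, SE 0.54, adjusted p = 1; 0.30 with the block). LHCGR was lower with PGF2A in numbers 1 to 3 and higher in number 4. STAR, CYP11A1, HSD3B1 and PTGFR were lower in every same-number pair, although none of them passed. PTGS2 (0.41), NR4A1 (0.37), VEGFA (0.11) and CXCL8 (-0.02) did not pass either, nor did ISG15 (0.68), MX1 (0.70), MX2 (0.71), OAS2 (1.17) or IRF9 (0.21).

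Some lists shifted together although few single members passed. The immediate early and NR4A list was higher (33 genes, median 0.16; camera adjusted p = 1.2e-08 and adjusted p = 0.018 with an estimated correlation and 0.051 with the block and an estimated correlation), with DUSP5 its 1 blocked call, and 2 with the block when adjusted over the list alone. Matrix and TGF-beta targets were higher (39 genes, median 0.10; camera adjusted p = 4.2e-05 and adjusted p = 0.33 with an estimated correlation); 3 members passed when adjusted over the list alone, and with the block 7 did and 2 over all genes. The cell cycle list was higher (30 genes, median 0.26; camera adjusted p = 2.8e-09 and adjusted p = 0.53 with an estimated correlation), with 1 member past the test over the list alone, and with the block 5 over the list alone and 1 over all genes. So was the interferon-stimulated list (54 genes, median 0.26; camera adjusted p = 2.5e-08 and adjusted p = 0.90 with an estimated correlation), of which 0 members passed in either fit. The latter difference varied between pairs, with list medians of -0.11, 0.31, 0.82 and -0.12 in numbers 1 to 4. The cholesterol list was lower (37 genes, median -0.09; camera adjusted p = 0.012 and adjusted p = 0.96 with an estimated correlation, 0.038 with the block and an estimated correlation). With the block, 5 more lists passed as lower, none of them with an estimated correlation: MHC class I (camera adjusted p = 0.048; 0.74 as adjusted p with an estimated correlation), steroidogenesis (0.036; 0.29), oxidative stress (0.029; 0.37), pericyte markers (0.049; 0.61) and large luteal markers (0.022; 0.13). With the block and adjusted over the list alone, rises and falls were 0 and 1 for cholesterol, 1 and 1 for steroidogenesis, 0 and 3 for oxidative stress, 1 and 4 for large luteal markers and 0 for the MHC class I and pericyte lists; over all genes, oxidative stress and large luteal markers had 1 fall each and the others 0.

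When PGF2A was added to IFNT, CCND1 was the 1 gene past the unblocked limma test on all 16 samples. It went from 495 ± 71.7 counts with IFNT to 1018 ± 147 with both (1.04, SE 0.13, adjusted p = 0.0087; higher in 4 of 4 pairs), with 356 genes at an unadjusted p under 0.05; edgeR on recovered reads also called 1 gene. Without number 4 in any group 0 genes passed in limma, with 443 at an unadjusted p under 0.05, and with only the 2 groups compared the 1 gene that passed was another. With the replicate block 99 genes passed, 78 higher and 21 lower. The authors' deposited table had 9 genes with an adjusted p under 0.05, 8 higher and 1 lower.

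The largest blocked rises were CD24 (1.99), the neuropeptide gene NPS (1.73), CYP17A1, an enzyme of androgen synthesis (from 80.9 ± 52.8 to 220.7 ± 129.7 counts), the epidermal growth factor family ligand EREG (1.44), MCOLN3 (1.32), ADGRE3 (1.26), the alarmin IL33 (1.23) and TMEM26 (1.15). The largest falls were FBXO10 (-0.97), FAM166B (-0.72), CRISPLD2 (-0.69), SLAIN1 (-0.68), GSTA2 (-0.66), SPOCK2 (-0.65), the collagen hydroxylase P4HA3 (-0.60) and CLDN11 (-0.52). SCG2 fell by 0.34 on the log2 scale, as in the comparison without IFNT. PTGS2, the inducible cyclooxygenase, rose from 686 ± 405 to 1136 ± 578 (0.77 and adjusted p = 0.016 with the block, 1.00 without).

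The immediate early list was higher here too (median 0.21; camera adjusted p = 6.0e-07 and adjusted p = 0.026 with an estimated correlation and 0.054 with the block and an estimated correlation), with DUSP5 (0.75), EGR1 (0.54) and EGR2 (0.69) past the blocked test over all genes and 11 of 33 members, all higher, when that test was adjusted over the list alone. Matrix genes were higher (median 0.12; camera adjusted p = 0.0021 and adjusted p = 0.57 with an estimated correlation), with 6 of 39 passing when adjusted over the list alone (9 with the block). In the blocked fit 5 members passed over all genes, among them MMP3 (1.06), MMP1 (0.77), BMP2 (0.67) and TIMP3 (0.38). The cholesterol list was lower (median -0.13; camera adjusted p = 0.0084 and adjusted p = 0.96 with an estimated correlation, 0.038 with the block and an estimated correlation), with MVK (-0.40) and FDFT1 (-0.26) falling and VLDLR (0.47) rising in the blocked fit, and 8 falls and 1 rise when adjusted over the list alone. The cytokine LIF (0.72) and the protease ADAMTS1 (0.48) also passed with the block. Pericyte and smooth muscle markers passed as lower in the blocked set test (median -0.18; camera adjusted p = 0.0076 and adjusted p = 0.39 with an estimated correlation). STAR (-0.06), CYP11A1 (-0.33), HSD3B1 (-0.26), LHCGR (-0.22), PTGFR (-0.70), NR4A1 (0.58), VEGFA (0.29), CXCL8 (0.08) and ISG15 (-0.16) did not pass in either fit, nor did MX1 (-0.13), MX2 (0.16), OAS2 (0.03) or IRF9 (-0.16). PTGFR was lower with both than with IFNT in numbers 1 to 3 and higher in number 4 (from 269.8 to 456.3 counts).

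Adding IFNT to PGF2A raised the same groups of genes as IFNT did alone. All 54 interferon-stimulated genes rose (median 3.77; camera adjusted p = 4.6e-56 and adjusted p = 0.062 with an estimated correlation). Among the largest rises were MX2 (8.69, SE 0.95), IFIT3 (8.44), RSAD2 (8.27), PLAC8B (7.98), GBP4 (7.93), IFIT2 (7.34) and the kinesin KIF5C (7.08). The largest falls were KCNF1 (-3.09), INSYN2 (-2.59), SAMD11 (-2.31), SYT6 (-2.19), the sodium channel SCN10A (-1.99), FITM2 (-1.98), SCRN1 (-1.97) and SVOP (-1.92). The unblocked limma test called 2948 genes, 1742 higher and 1206 lower, and the blocked test 5696 (2949 higher, 2747 lower). At least 2-fold were 1023, of which 809 were higher.

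MHC class I genes rose in 19 of 21 cases (camera adjusted p = 1.4e-20 and adjusted p = 0.027 with an estimated correlation, 0.11 with the block and an estimated correlation), with TAP1 at 3.33 and PSMB9 at 3.40. Of 11 class II genes 6 rose, 7 when adjusted over the list alone (camera adjusted p = 2.9e-06 and adjusted p = 0.17 with an estimated correlation), among them the class II transactivator CIITA (2.57). JAK-STAT and IRF genes had 13 rises and 2 falls of 29, 16 and 4 with the block (camera adjusted p = 6.0e-05 and adjusted p = 0.53 with an estimated correlation), with IRF1 at 2.09. Inflammatory genes had 20 rises and 0 falls of 40 (camera adjusted p = 3.3e-07 and adjusted p = 0.23 with an estimated correlation, 0.038 with the block and an estimated correlation), with ICAM1 at 1.25. Apoptosis genes had 15 rises and 1 fall of 34, 16 and 4 with the block (camera adjusted p = 0.0024 and adjusted p = 0.035 with an estimated correlation, 0.051 with the block and an estimated correlation), with CASP4 at 2.27 and FAS at 1.59. The cholesterol list had 5 rises and 0 falls of 37, and 20 rises and 3 falls with the block (camera adjusted p = 0.026 and adjusted p = 0.96 with an estimated correlation, 0.038 with the block and an estimated correlation), including the lysosomal lipase LIPA (0.97). The cell cycle list was lower (median -0.59, 1 rise and 1 fall of 30; camera adjusted p = 0.015 and adjusted p = 0.96 with an estimated correlation); blocked counts were 3 higher and 22 lower. Adjusted over the list alone, rises and falls were 21 and 0 for MHC class I, 14 and 2 for JAK-STAT and IRF genes, 22 and 0 for inflammatory genes, 16 and 3 for apoptosis, 5 and 0 for cholesterol and 0 and 1 for the cell cycle. With the block, adjusting over the list alone moved no count of rises or falls of a list by more than 3.

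CYP11A1 fell from 28350 ± 7230 counts with PGF2A to 13050 ± 2855 with both (-1.11, SE 0.21, adjusted p = 0.0012), and NR5A1 by 0.70 on the log2 scale. Of 32 steroidogenesis genes 2 rose and 4 fell, 6 and 13 with the block. STAR (-0.59 and adjusted p = 0.51, or 0.00017 with the block), HSD3B1 (-0.38; 0.28, or 0.014), PTGS2 (-0.42; 0.59, or 0.018), NR4A1 (-0.69; 0.18, or 0.00084) and VEGFA (-0.54; 0.44, or 0.0061), with adjusted p in the same order, passed with the block alone. LHCGR (-0.02), PTGFR (0.55) and CXCL8 (-0.14) passed in neither. Endothelial markers ERG (1.30) and TEK (1.11) rose, and with the block 10 of 12 rose (camera adjusted p = 0.00083 and adjusted p = 0.63 with an estimated correlation). Of 27 glycolysis genes 2 rose and 3 fell, and the blocked list was again lower (5 higher, 13 lower; camera adjusted p = 0.038 and adjusted p = 0.74 with an estimated correlation).

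The design also asks whether the treatments modify each other. No gene passed the limma test of the interaction, with or without the replicate block (40 and 219 genes at an unadjusted p under 0.05), and edgeR, DESeq2 and the authors' deposited table also gave 0. On simulated data the unblocked test found 35.5% of 2-fold interactions and the blocked test 75.8%, so smaller ones were often out of reach. As lists, the interferon-stimulated genes had a smaller rise with IFNT when PGF2A was present (median -0.20, camera adjusted p = 5.5e-10 and adjusted p = 0.82 with an estimated correlation). Cell cycle genes instead had a larger fall with IFNT (median -0.22, camera adjusted p = 0.0025 and adjusted p = 0.96 with an estimated correlation). Their median was -0.36 for IFNT against control and -0.59 for IFNT+PGF2A against PGF2A. For PGF2A it was 0.26 against control and 0.07 when added to IFNT, where the list did not pass (camera adjusted p = 0.24). For the interferon-stimulated list, the level reached with IFNT hardly differed when PGF2A was added (IFNT+PGF2A against IFNT, median -0.01, camera adjusted p = 0.53). The list was higher in PGF2A than in control in numbers 2 and 3 (pair medians 0.31 and 0.82). In numbers 1 and 4 it was not (-0.11 and -0.12). Over both IFNT states, the main effect of PGF2A passed for 4 genes, all higher: CCND1 (0.96), PHLDA1 (0.46), the fibroblast growth factor FGF7 (0.64) and TCHHL1 (3.10), of which all but CCND1 were named after their values were seen. Leaving out 1 library gave 1 to 8 genes. The blocked count was 277 (181 higher, 96 lower), and the authors' deposited table had 26. The main effect of IFNT passed for 5444 genes, 2745 higher and 2699 lower (3870 and 4192 with the block).

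Across 14122 genes, which are not independent replicates, the IFNT effects without and with PGF2A correlated at r = 0.955 (Spearman 0.902). Both comparisons called 2608 genes, all with the same sign (1580 higher and 1028 lower; independent lists would share 228 and 131). Of the 2 PGF2A effects, without and with IFNT, r was 0.466 (Spearman 0.520). In the blocked fits, 16 genes passed in both, all with the same sign (13 higher and 3 lower; independent lists would share 0.088 and 0.010). These pairs of comparisons share no libraries, but they share each gene's estimate of the spread and the same sample numbers. Overlap above that of independent lists can therefore come in part from genes with a small spread. The IFNT and PGF2A effects, both set against the same controls, had r = 0.0143 (Spearman -0.053). Groups simulated with no effect of either treatment, against shared controls, gave r = 0.499. IFNT changed many genes here, which the simulation leaves out, so its r and share of same signs are no reference for the observed ones. The covariance of the observed effects was 0.00251 against a simulated 0.0203, a difference of -0.0177. With the controls split between the comparisons r lay between -0.0997 and 0.0859 in 6 splits. Of the genes, 47.9% had the same sign. The simulation without effects gave 66.8%, which is no reference for that share.

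**Figure D3:**
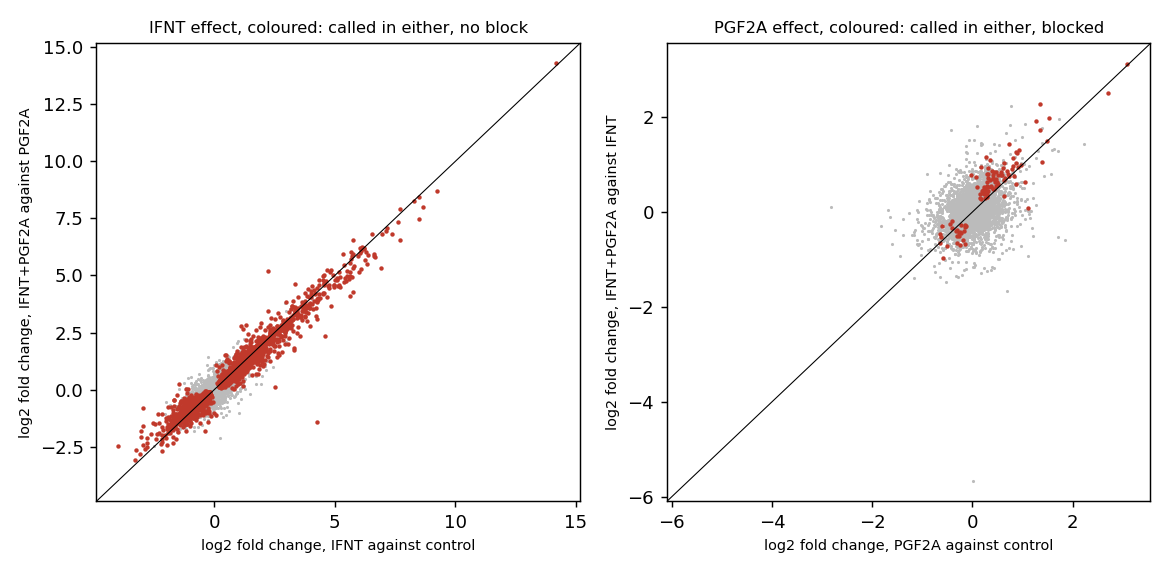
Log2 fold changes of 14122 genes; left, IFNT effect without PGF2A (horizontal) against with PGF2A (vertical), right, PGF2A effect without IFNT (horizontal) against with IFNT (vertical), with the line of equality. Red genes passed in either comparison, without the block on the left and with it on the right; all genes give r = 0.955 on the left and 0.466 on the right.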

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

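The tests of explanations for the 3 patterns weighed here, and the choice of most genes examined beyond those always named, were made only after the values were seen; the tests of the interaction were chosen before.

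Among 140 groups of 4 libraries, of reported genes, read totals and shares, 10 had 1 library far from the other 3 by Dixon's criterion, and chance flags about 1 in 20 groups. IRF9 was at 1305 normalized counts in control replicate 1, against 946.8 to 963.8 in the other control libraries. PTGS2 was at 1998 in IFNT+PGF2A replicate 3, against 776.4 to 920.7. CCND1 was at 1238 in IFNT+PGF2A replicate 2, against 929.6 to 959.1. CLDN11 was at 2496 in IFNT replicate 3, against 1405 to 1467. HBA was at 1640 in IFNT replicate 2, against 64.6 to 254.7. For PTGS2 and CLDN11 replicate 3 was the highest library in every group, and for HBA replicate 2 was. Those values therefore follow the sample number and are not odd single libraries. For IRF9 and CCND1 the flagged number was not the highest in every group. HBA1 was at 23.95 in control replicate 1 and at 24.83 in PGF2A replicate 3, against 0 in the other libraries of each group. HBB was at 0 in IFNT replicate 1 against 0.977 to 1.03, at 0.984 in PGF2A replicate 4 against 0, and at 1.01 in IFNT+PGF2A replicate 2 against 0. These HBB values lie under the floor of 3 reads and carry no weight.

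In the interaction, 2 lists differed between the states with and without PGF2A by the camera test. The rise of interferon-stimulated genes with IFNT was smaller with PGF2A (adjusted p = 5.5e-10, median of 54 genes -0.20). The fall of cell cycle genes with IFNT was larger with PGF2A (adjusted p = 0.0025, median of 30 genes -0.22). No member passed on its own in limma, with 40 genes of all those tested at an unadjusted p under 0.05, and neither list passed with an estimated correlation (adjusted p = 0.82 and 0.96).

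The first pattern lies behind the interferon-stimulated list. Its genes were higher than control in PGF2A replicate 3 (median 0.82, 50 of 54 members higher) and less so in replicate 2 (0.31, 45 of 54). In replicates 1 and 4 the medians were -0.11 and -0.12, with 12 and 18 members higher. Against a response to PGF2A in every culture stands the lowest of these medians, -0.12. Against RNA or reads carried over from an IFNT library stands 786073. It had 9712 reads in IFNT replicate 3, and a carry-over at the list's median share of the IFNT gain (5.29%) would bring 513 reads to PGF2A replicate 3, which had 0. That allows a share of at most 0.0309%. The share also differed between members, from 0.232% at the 10th percentile to 11.75% at the 90th. A difference of that culture, such as a trace of interferon acting on its cells, may remain and was not tested. The 0 reads of 786073 gave no sign of such a trace. That is 1 gene of unknown identity, and its response to a low dose is not known.

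The second pattern is alpha globin. HBA had 44 to 4193 reads in every library, 17256 alpha globin reads in all with HBA1. Against red blood cells in the cultures stand the 3 beta globin genes, with 8 reads in all, or 0.0464 per 100 alpha globin reads. HBA1 was at 24 or 25 reads in 6 libraries and at 0 in the other 10, so its changes may come from the sharing of reads with HBA, which was not tested. No explanation by expression in the luteal cells was tested.

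The third pattern is the distance of number 4 from the other numbers on the second principal component. The total of number 4 lay above those of the others in 3 of 4 groups and inside their range in control. A difference in library size is argued against as the whole cause, since the relation of this component to the total within groups, over the 12 libraries numbered 1 to 3, allows at its 95% limit at most 27.18% of the distance of number 4 in any group. This test replaced a first one that rested on the range alone. A few genes taking most of the counts are argued against, since the 10 highest genes took at most 10.4% of the reads in any library. Their share was highest in number 4 of every group, by at most 1.395 percentage points over the highest of numbers 1 to 3. A lower share of luteal cells would raise the markers of every other cell type alike. The pericyte and smooth muscle list was higher by 0.93 ± 0.15 and the macrophage list differed by -0.04 ± 0.17 (log2, SD over 4 groups), a gap of 0.969 with an SD of 0.230. The criterion first written for this test, 1 list below 0 and 1 above by more than their SD, was not met, and the gap was taken as the criterion after the values were seen. The fibroblast and endothelial lists differed by 0.32 and 0.04. In the direction of a lower luteal share, the steroidogenesis list differed by -0.16 ± 0.04, the large luteal list by -0.30 ± 0.12 and the small luteal list by -0.21 ± 0.15, each below 0 in all 4 groups. The SD of the gap is over treatments of 1 number, which the data pair, and such gaps among numbers 1 to 3 were not examined. Whether a gap of 0.969 is unusual between numbers is therefore unknown. The gap does not decide the question, and a lower share of luteal cells stays open. A larger share of pericytes or smooth muscle cells in number 4, or another difference between cultures, may stand behind its distance, and neither was tested.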

How the results depend on the processing

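Chosen only after seeing the data were the pseudocounts of 1 and 5, edgeR and DESeq2 on recovered reads, the authors' deposited adjusted p, the fits without number 4, fry, and the blocked set test with an estimated correlation. So were the correlations of effects over genes called with the block. Counts come in the order IFNT against control, PGF2A against control, IFNT+PGF2A against IFNT, IFNT+PGF2A against PGF2A, interaction, main effect of PGF2A and main effect of IFNT, where all 7 are given. The limma test gave 3384, 0, 1, 2948, 0, 4 and 5444.

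With the replicate block the counts were 6140 for IFNT against control, 23 for PGF2A against control, 99 for IFNT+PGF2A against IFNT, 5696 for IFNT+PGF2A against PGF2A and 277 for the main effect of PGF2A. With edgeR and the replicate block they were 6125, 28, 91, 5738 and 292. Pairing removes the difference between numbers from the error, and the median standard error went from 0.178 to 0.115. Of the set tests and the genes named in the report, the block changed no other call than those given with it More members passed with it in 23 of the 25 lists for IFNT against control and 21 of 25 for IFNT+PGF2A against PGF2A. With the block and without number 4 they were 7925, 96, 334, 7587 and 794, and 9422 for the main effect of IFNT; the cause was not tested. Without number 4 and unblocked, 0 genes passed in limma for IFNT+PGF2A against IFNT (443 at an unadjusted p under 0.05).

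The count of PGF2A against control was 2 with no filter, 1 at an adjusted p under 0.10, 2 with DESeq2 on all samples, and 5 both with DESeq2 on the 2 groups and in the authors' deposited table. That of IFNT+PGF2A against IFNT was 9 with DESeq2 either way and in the authors' table, and the main effect of PGF2A had 50 genes with DESeq2, 26 in the authors' table and 8 at an adjusted p under 0.10; the cause was not tested. With only the 2 groups compared, IFNT against control had 2118 genes, 2099 of them shared with the 16-sample fit, and the 1 gene of IFNT+PGF2A against IFNT was not CCND1.

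Stricter criteria lowered counts by construction. At an adjusted p under 0.01, IFNT against control had 1963 genes, IFNT+PGF2A against PGF2A 1733 and the main effect of PGF2A 1. At least 2-fold were 1138, 1023, 1 and, for the main effect of IFNT, 1224. Against a null of at most 1.2-fold they were 1460, 1238, 1 and 2243, with 0 for IFNT+PGF2A against IFNT (76 at an unadjusted p under 0.05). Rescaling statistics by their robust spread takes that spread from all genes, changed ones included, and gave 1, 68, 1, 1, 26, 1 and 0, with 1 of 185 named calls kept.

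Across genes, the correlation of IFNT effects with and without PGF2A was 0.963 at a mean of at least 10, 0.980 at a mean of at least 50, 0.902 by Spearman, 0.980 over called genes and 0.972 over genes called with the replicate block. For PGF2A effects it was 0.637 at a mean of at least 50, 0.520 by Spearman and 0.899 over genes called with the block. For IFNT beside PGF2A it was -0.053 by Spearman and 0.094 over called genes. Called genes were picked by these same effects, which can by itself raise r, so these values are not comparable with those over all genes. Of 125 set tests 25 passed with camera, 6 with an estimated correlation, 16 with a preset of 0.05, 5 with the block and an estimated correlation, 16 with fry and 40 with fry and the block. The 6 were MHC class I and apoptosis in both IFNT comparisons and the immediate early list in both PGF2A comparisons. Of 45 tests of cell type markers 0 passed with camera, 2 with ranks, 5 with the block, 2 with fry and 9 with fry and the block.

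Leaving out 1 library at a time gave 2746 to 4273 genes for IFNT against control, 0 to 1 for PGF2A against control (1 without IFNT+PGF2A replicate 2), 1 to 2 for IFNT+PGF2A against IFNT (2 without PGF2A replicate 2), 2129 to 4094 for IFNT+PGF2A against PGF2A, 0 for the interaction, 1 to 8 for the main effect of PGF2A and 4823 to 6431 for the main effect of IFNT. The main effect of PGF2A had 8 genes without IFNT replicate 4, 2 without control replicates 3 or 4, IFNT replicate 3 or PGF2A replicates 1 or 2, 5 without control replicate 2, and 1 without any of the other 9 libraries. Leaving out a number gave correlations of 0.936 to 0.946 for IFNT, 0.376 to 0.475 for PGF2A and -0.036 to 0.076 for IFNT beside PGF2A, 25 to 28 lists and 0 to 5 marker lists.

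No count moved by over 1.5 times with the pseudocounts, a mean of at least 10 or unblocked edgeR, and no named call reversed its direction in any alternative. Of the 185 named calls, 185 held with the block, 178 with only the 2 groups, 164 at an adjusted p under 0.01, 183 with DESeq2 and 182 in the authors' tables. Adjusting the authors' p-values over all genes and a baseMean of at least 50 apply only to their statistics and were not run. Depth limits low genes, as a count of 0 in a group still allows 3 reads.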

Other observations

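The genes named here and the tests on them were chosen only after their values were seen, while the counts over other splits of the samples were planned before, except the swaps for the main effect of IFNT.

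Among the genes outside the fixed lists, 786073 had the widest contrast. It had 0 reads in the 8 libraries without IFNT, 7591 to 12102 with IFNT and 8095 to 13824 with both, at least 14088-fold above PGF2A at a floor of 3 reads over the group. The table lists it by number only and the RefSeq gene table has no entry for it, so what it encodes was not determined.

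Other splits of the same samples showed how often counts as large arise when the labels are mixed. The treatment effects stay in such data and can widen the spread within mixed groups, so these are not counts without treatment. For IFNT against control 1 of 35 splits gave 3384 genes, the real one, and the highest other gave 1114. That other split does not part all 4 pairs of numbers, and among the splits that do, the highest other gave 0. For IFNT+PGF2A against PGF2A 1 of 35 gave 2948, with 0 the highest other, and for the main effect of IFNT 1 of 100 draws gave 5444, with 26 the highest other. These 3 shares are under 0.05 over splits that ignore the pairing of the numbers. The splits of either pair of groups that part all 4 pairs of numbers are 8, too few for a share under 0.05, and the highest other among them was 0 for both. For the main effect of IFNT, swaps within number and PGF2A state with the replicate block keep the pairing. Of 100, 1 gave 8062 genes, the real one, and the highest other gave 4667. Both pairs of a number were swapped separately here, so a share under 0.05 holds only if they count as independent. Swapping whole numbers would leave too few splits for such a share, so chance is not excluded over numbers. Chance was not excluded for IFNT+PGF2A against IFNT without the block (real 1, highest other 4, 2 of 35). For PGF2A against control (highest other 1, 35 of 35 as large) and the interaction (highest other 25, 100 of 100) the real limma count was 0, with 155 and 40 genes at an unadjusted p under 0.05. Every split is as large as 0, so these counts say nothing about chance.

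For the main effect of PGF2A 3 of 100 draws, which ignore the pairing, gave 4 genes or more, and the highest other gave 1387, many times the real count. These draws shuffled the labels of all 16 samples, IFNT among them, so a drawn grouping can take in part of the IFNT effect. They therefore cannot decide about PGF2A alone, and what the draw with 1387 genes parted was not examined. With swaps within number and IFNT state and the replicate block, 1 of 100 gave 277 genes, the real one, and the highest other gave 3. Both pairs of a number were swapped separately, so this share under 0.05 holds only if they count as independent. With whole numbers swapped the splits would be too few for such a share, so chance is not excluded over numbers. In the blocked comparisons of PGF2A against control (real 23, highest other 1, 1 of 8 swaps) and IFNT+PGF2A against IFNT (real 99, highest other 0, 1 of 8), the splits are too few for a share under 0.05.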
